A study of Homo sapiens with 8 samples.

How the data were processed

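Whole-genome bisulfite sequencing (WGBS, in which unmethylated cytosines are read as thymines) and RNA sequencing were done on 4 stable clones of HEK293, a human embryonic kidney cell line. Clones G13 and G17 carried a GFP control construct, and clones S27 and S29 carried GFP fused to S-adenosylhomocysteine hydrolase (SAHH), the enzyme encoded by AHCY. Groups were taken from the overexpression field of the sample labels. Each clone is 1 sample per assay, and the labels' protocols describe clones as picked single colonies, so the replicates are clones of one parental line. The tests of tiles and bins described below also borrow the spread of all tiles or bins. Replicates 1 and 2 of the controls are G13 and G17, and those of the SAHH group are S27 and S29. These replicate numbers carry no pairing between the groups.

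For WGBS, the submitters' processing notes name Trim Galore, Bismark and Bowtie2 and the build hg19, with no versions. The deposited coverage files give for each CpG cytosine the counts of methylated and unmethylated calls, with no normalization, and the authors' percent of methylated calls, which equals the methylated count over the sum of both counts in each row. Removal of duplicate reads is not given in the sources used here. For RNA, the submitters' processing notes name TopHat2, HTSeq and DESeq2. Per the file headers, the authors' deposited table gives per gene a mean normalized signal over all samples, a log2 fold change, its standard error on the log2 scale, a test score and a p-value with its adjusted p-value. The header has 1 name fewer than the columns, since row names come first. The table holds comparison values, and expression values per clone were not used here. Its adjusted p-values are those of a Benjamini-Hochberg adjustment of the p-values over 14227 genes (the p-value times 14227 over its rank, or that of a later rank where this is lower), so the authors' adjustment ran over 14227 genes and the 100 listed genes are those with an adjusted p under 0.1. The columns do not name the group in the numerator. Positive log2 fold changes are taken as higher in SAHH clones because AHCY, the overexpressed gene, has a positive value. Of the 100 symbols, 94 are current and 6 were matched as older symbols in a RefSeq gene table of GRCh38.p14, which was used for names only.

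The files of G13, G17 and S27 held rows at positions that cannot be right. They listed 885910, 381716 and 242088 rows past the last position of the S29 file on a chromosome by over 10 kb, and further rows in 19 stretches of over 1 Mb without an S29 site, where the S29 file had none. From the density of such rows, 11.9% of the G13 rows, 7.16% of the G17 rows and 3.18% of the S27 rows were estimated to carry a wrong position. Those in the 19 stretches averaged 1.05, 1.03 and 1.03 calls in G13, G17 and S27, and the methylation of those past the chromosome ends was 67.8%, 63.5% and 70.7%. For this reason all WGBS results use the 45749911 CpG cytosines of chromosomes 1 to 22 and X that the S29 file lists. That choice was made after the files were seen and before any comparison between groups, and results with the files as deposited are given among the alternatives. It kept 130868902 calls in G13, 58906455 in G17, 187933244 in S27 and 168682065 in S29. Rows kept were 38251841 of 49409459 in G13, 29355597 of 35538535 in G17 and 41420366 of 49634204 in S27. More rows were dropped than were estimated as misplaced, so the sites were also chosen by coverage in S29, an SAHH clone. Of the listed sites 83.6% were covered in G13, 64.2% in G17 and 90.5% in S27. For the same reason CpG density was counted from these cytosines, where the plan was to count those of all files together. Very deep sites, left out in some alternatives, are those with over 24 calls in G13, 10 in G17, 30 in S27 or 27 in S29.

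Methylation levels were computed as methylated calls over all calls. Group means are given with the SD over 2 clones. An exact two-sided permutation test of the 4 clones has 6 labelings and cannot give a p under 0.333. The genome was divided into 1 kb tiles, tiles were classed by their number of listed CpG cytosines on both strands, and tiles with at least 20 calls in each clone and at least 4 CpG cytosines were tested (1098075 of 2785273). The test was a quasi-binomial logistic model with the group as the factor, with the dispersion moderated by squeezeVar of limma 3.58.1 in R 4.3.3 and held at 1 or more, an F test and Benjamini-Hochberg adjustment. For tiles the prior dispersion had 13.9 degrees of freedom, against 2 from a tile's own clones. The p-values thus rest mostly on a spread pooled over tiles. A tile was called at an adjusted p under 0.05 and a difference of at least 10 points. The same test was run on 100 kb bins with at least 1000 calls in each clone, with no minimum difference. edgeR 4.0.16 was run on methylated and unmethylated counts as an alternative. Further alternatives changed the minimum of calls, the minimum difference, the tile and bin size, the dispersion, the depth, the sites used and the clones included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

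The tile test was tested on simulated data, with calls drawn for all 1098075 tested tiles at their own depths and 200 tiles changed. With 1 dispersion factor at all depths, it recovered 88 of 100 tiles changed by 50 points and 13 of 100 changed by 25 points, with 2 false calls. With 1 correlation between calls at all depths, so that the dispersion grows with depth, it recovered 84 and 4 of 100 with 16 false calls. Moderation of the dispersion along depth then recovered 93 and 3 of 100 with 0 false calls. That form was therefore added as an alternative after the data were seen.

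Before the data were examined, the tests, the gene lists and the rule for named items were fixed. For expression, the rule names the 15 genes with the highest and the 15 with the lowest log2 fold change at an adjusted p under 0.05, plus each gene of the fixed lists that is in the table. For tiles it names up to 5 gained and 5 lost ones with the largest difference, at least 50 calls in every clone, both SAHH clones on the same side of both controls and over 5 kb apart. For chromosomes it names the highest and the lowest difference. Planned comparisons over promoters, exons and introns, of expression with promoter methylation, and of calls in AHCY exons against introns needed an hg19 gene annotation, and these are not analysed here. Counts adjusted over the list alone could not be computed for the gene lists, since the table does not list genes past an adjusted p of 0.1. Coordinates are 1-based on hg19, as in the deposited files.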

Results

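CpG methylation was measured by WGBS in 2 control clones (G13 and G17) and 2 SAHH clones (S27 and S29) of HEK293, and expression was measured by RNA-seq in the same 4 clones. SAHH hydrolyses S-adenosylhomocysteine, the product and inhibitor of methyltransferase reactions, and the comparison asks whether a higher level of SAHH changes CpG methylation. The coverage files held 148882446 calls for G13, 67866949 for G17, 207730300 for S27 and 171410580 for S29. After restriction to the CpG cytosines of the S29 file, the mean was 2.86 calls per cytosine in G13, 1.29 in G17, 4.11 in S27 and 3.69 in S29. At this depth single cytosines were not compared, and levels were taken over tiles, bins, chromosomes or the genome. Expression was available as the authors' deposited table of 100 genes.

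Total CpG methylation was higher in both SAHH clones than in both control clones. It was 67.4% of calls in S27 and 66.7% in S29, against 64.0% in G13 and 60.8% in G17. The SAHH mean was 67.1% ± 0.51 (SD, n = 2) and the control mean 62.4% ± 2.24 (SD, n = 2), a difference of 4.66 points. The difference exceeded the SD of either group, and the exact two-sided permutation p was 0.333, the smallest that 2 clones against 2 can give. Without G17, the shallowest clone and the one with the lowest level, the difference was 3.08 points.

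The difference was seen on each of the 23 chromosomes compared, with both SAHH clones above both controls on chromosomes 1 to 22 and X. It was highest on chromosome 16, where methylation was 54.7% ± 1.28 in SAHH clones and 47.1% ± 1.68 in controls (SD, n = 2 each), a difference of 7.61 points. Much of chromosome 16's coverage came from deep sequence at 46300001 to 46500000, and without very deep sites the chromosome 16 difference was 4.31 points and that of chromosome 4, at 5.04 points, was the highest. Over the sites with at least 5 calls in every clone (686917 of 45749911 on all chromosomes) chromosome 10 was highest, at 6.96 points against 6.93 on chromosome 16. It was lowest on chromosome 21, at 61.4% ± 0.68 in SAHH clones and 59.1% ± 1.31 in controls, a difference of 2.29 points. Over the chromosome 21 sites with at least 5 calls in every clone it was 0.19 points, and the clones then overlapped. The X chromosome had the lowest level in all 4 clones, with 37.5% ± 0.11 in SAHH clones and 33.6% ± 1.81 in controls. The 23 chromosomes are not independent replicates, and their shared order adds nothing to that of the clones' total levels.

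**Figure D1:**
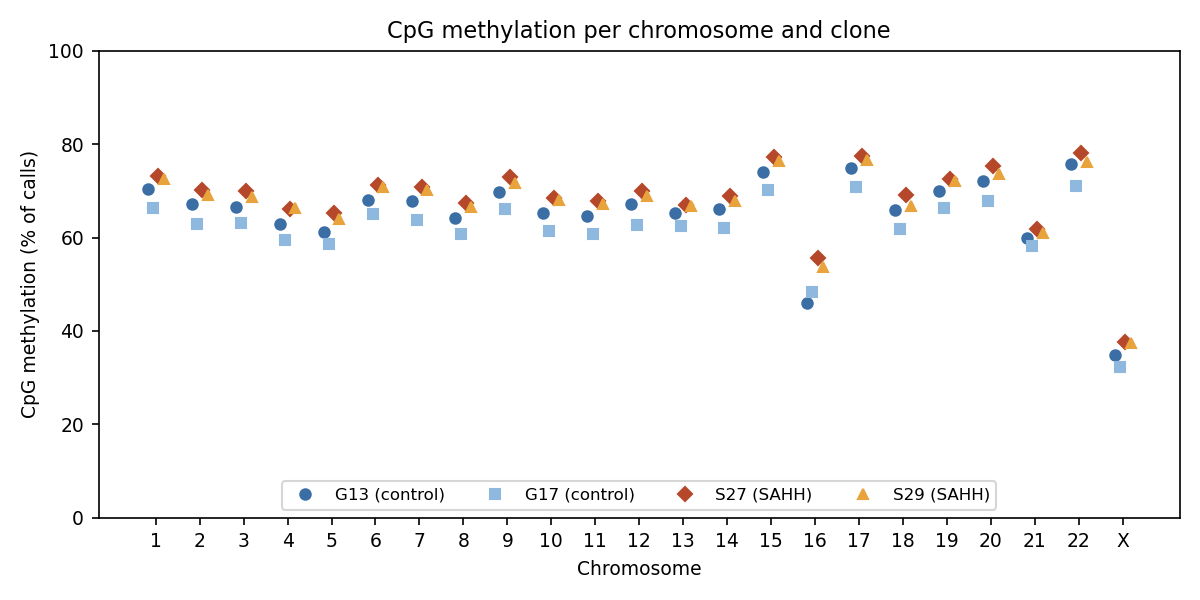
CpG methylation (percent of calls, y axis) of each chromosome (x axis) in control clones G13 and G17 and SAHH clones S27 and S29, 1 point per clone. Both SAHH clones lie above both control clones on all 23 chromosomes, and the X chromosome is lowest, at 32.3% to 37.6%.

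Both CpG-poor and CpG-dense sequence had higher methylation in SAHH clones. In 1 kb tiles with 1 to 9 CpG cytosines the SAHH mean was 55.6% ± 0.45 and the control mean 50.7% ± 2.68, a difference of 4.81 points (SD, n = 2 each, here and in the other classes). The differences were 4.79 points with 10 to 19 CpG cytosines, 4.25 points with 20 to 39 and 4.69 points with 40 to 79. In the densest class, with 80 or more CpG cytosines per kb, which stands in for CpG islands here, the level was 30.8% ± 1.00 in SAHH clones and 25.3% ± 2.25 in controls, a difference of 5.47 points. Without very deep sites that difference was 3.38 points, and over sites with at least 5 calls in every clone it was 8.81 points. The exact permutation p was 0.333 in each class, and both SAHH clones were above both controls in each. Without G17 the 5 differences were between 2.42 and 3.88 points.

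Tiles over 80% methylated were more common in SAHH clones, and tiles of intermediate level were fewer. Of 1098075 tiles, 52.0% ± 1.65 were over 80% methylated in SAHH clones and 40.9% ± 7.26 in controls (SD, n = 2 each), a difference of 11.1 points. Tiles of 20 to 80% made up 40.6% ± 1.38 in SAHH clones and 49.6% ± 5.49 in controls. Tiles under 20% made up 7.42% ± 0.27 in SAHH clones and 9.45% ± 1.77 in controls. Without G17 the differences were 5.94 points in tiles over 80%, -5.17 points in tiles of 20 to 80% and -0.777 points in tiles under 20%. Over the 157581 tiles with at least 50 calls in each clone they were 9.15, -7.24 and -1.91 points. Shares past a fixed level also depend on the calls per tile, and both controls were shallower than both SAHH clones. The shares were not compared at equal depth, so the part that depth has in them is not known. Grouped by their mean level over all 4 clones, tiles of 60 to 70% were at 68.4% ± 1.34 in SAHH clones and 62.4% ± 4.86 in controls, with G13 at 65.8% and G17 at 58.9%. Tiles of 0 to 10% differed by 2.02 points and tiles of 90 to 100% by 1.03 points.

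**Figure D2:**
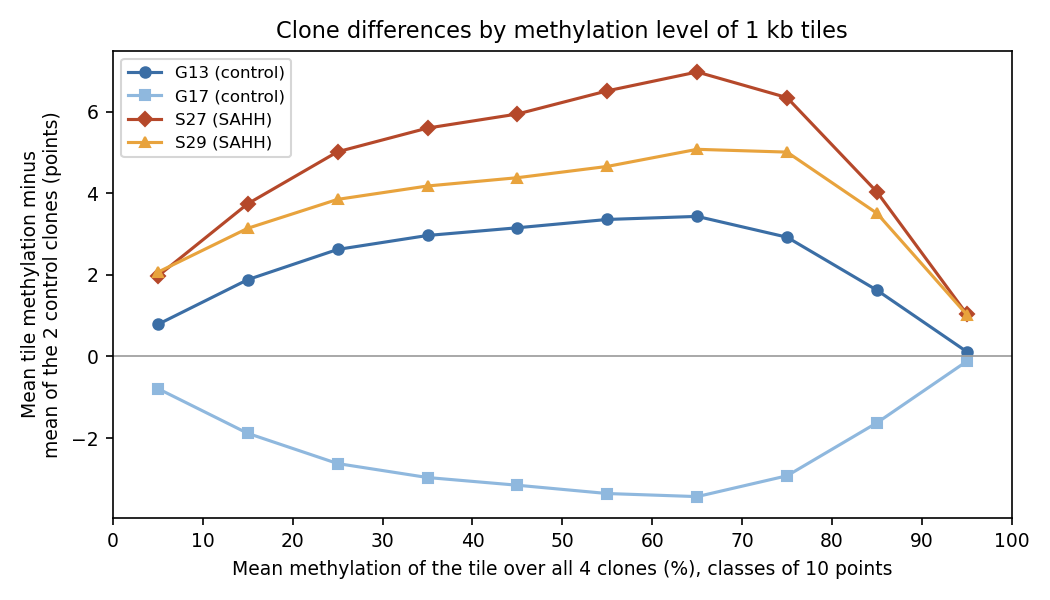
Mean methylation of 1 kb tiles in each clone minus the mean of the 2 control clones (points, y axis), in classes by the tile's mean level over all 4 clones (percent, x axis), 1 line per clone. At 60 to 70% the SAHH-minus-control difference is 6.03 points, and at 90 to 100% it is 1.03 points, while G13 and G17 lie on either side of 0 by construction.

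Few single tiles could be called. Of 1098075 tiles, 3 were called as gained in SAHH clones and 0 as lost by the quasi-binomial test with limma's moderated dispersion, with 74338 tiles at an unadjusted p under 0.05. edgeR called 0 in either direction, with 65690 at an unadjusted p under 0.05. The rule names 2 of the 3. The tile on chromosome 19 from 38432001 to 38433000 had 59.1% ± 11.1 methylation in SAHH clones and 8.60% ± 0.96 in controls (SD, n = 2 each), with 97 to 218 calls per clone and an adjusted p of 0.0335 in the limma-moderated test. The tile on chromosome 16 from 46413001 to 46414000 had 30.9% ± 0.86 in SAHH clones and 20.4% ± 4.31 in controls, with 8073 to 23292 calls per clone and an adjusted p of 0.0348 in the same limma-moderated test. The third, on chromosome 7 from 130628001 to 130629000, is named after its values were seen, since G17 had 32 calls there. It had 71.8% ± 3.23 in SAHH clones and 16.04% ± 3.83 in controls, with an adjusted p of 0.0195 in the limma-moderated test. With the dispersion moderated along depth no tile was called, and the adjusted p of the chromosome 7 tile was 0.051. Without G17, S27 or S29 no tile was called either, and without G13 51 were called as gained and 9 as lost. Over all tested tiles, both SAHH clones were above both controls in 31.2% and below both in 6.78%, where clones with no overall difference would give 16.7% for each.

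The difference was broad over 100 kb bins. Of 25625 bins, 77.7% had both SAHH clones above both controls and 0.57% had both below, where clones with no overall difference would give 16.7% for each order. The bins share the same 4 clones and so do not add to the single order of the clones' total levels. The median difference was 4.49 points, with quartiles of 3.43 and 5.62 points, and it was 2.39 points without G17. By the limma-moderated test 13 bins were called higher and 2 lower in SAHH clones. With the dispersion moderated along depth 9 were called higher and 8 lower, the lower ones on chromosomes 7, 8, 13, 18 and 21. In the chromosome 8 bin the groups overlapped, with S29 at 44.7% and control G17 at 42.35%. S27 lay just below G17 on chromosome 7 from 14800001 (42.73% and 44.23%) and on chromosome 21 from 18400001 (51.78% and 52.41%). On chromosome 21 from 18200001 the SAHH clones were far apart, with S29 at 34.76% and S27 at 55.40%. In the lower bins of chromosomes 13 and 18 the groups lay further apart. The bin called higher with the largest difference, on chromosome 7 from 136600001, had the controls far apart, with G13 at 60.7% and G17 at 33.35%.

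The 2 lower bins were neighbours on chromosome 13. From 86200001 to 86300000 methylation was 51.1% ± 0.08 in SAHH clones and 70.8% ± 1.03 in controls, and from 86300001 to 86400000 it was 46.6% ± 2.32 and 66.4% ± 0.29 (SD, n = 2 each). Both had an adjusted p of 0.0303 in the limma-moderated test and 1001 to 3346 calls per clone. Of the 13 higher bins, 3 had 1138 to 4614 calls per clone. These were on chromosome 4 from 21200001 to 21300000, at 77.4% ± 1.40 in SAHH clones and 62.3% ± 6.90 in controls, on chromosome 4 from 21400001 to 21500000, at 74.3% ± 0.81 and 58.4% ± 5.68, and on chromosome 5 from 86000001 to 86100000, at 69.7% ± 4.26 and 52.4% ± 7.67. These 5 bins were called also with the dispersion moderated along depth, where their adjusted p-values by the limma-moderated test were between 0.00743 and 0.00929. With any 1 clone left out none of the 5 was called, except the chromosome 5 bin without S27 (limma-moderated adjusted p 0.0409), and the other adjusted p-values were between 0.0765 and 0.643.

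The other 10 higher bins had 7280 calls or more in every clone. The deepest were on chromosome 16 from 46300001 to 46400000, where methylation was 21.6% ± 0.68 in SAHH clones and 14.5% ± 3.29 in controls, and the next bin, where it was 23.4% ± 0.74 and 16.1% ± 3.81 (SD, n = 2 each). These chromosome 16 bins alone held 0.73% and 0.63% of all calls of the clones, on 1143 and 5182 CpG cytosines. Chromosome 10 from 42300001 to 42400000 had 34.7% ± 0.72 in SAHH clones and 25.3% ± 6.48 in controls. Without G17 the difference fell from 7.01 to 4.69 and from 7.33 to 4.64 points in the chromosome 16 bins. In the chromosome 10 bin it fell from 9.41 to 4.83 points. With the dispersion moderated along depth none of these 10 bins was called. In the limma-moderated test 0 bins were called without G13 (14491 at an unadjusted p under 0.05) and 0 without G17 (3948), without S27 24 were called higher and 34 lower, and without S29 6 higher and 1 lower.

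**Figure D3:**
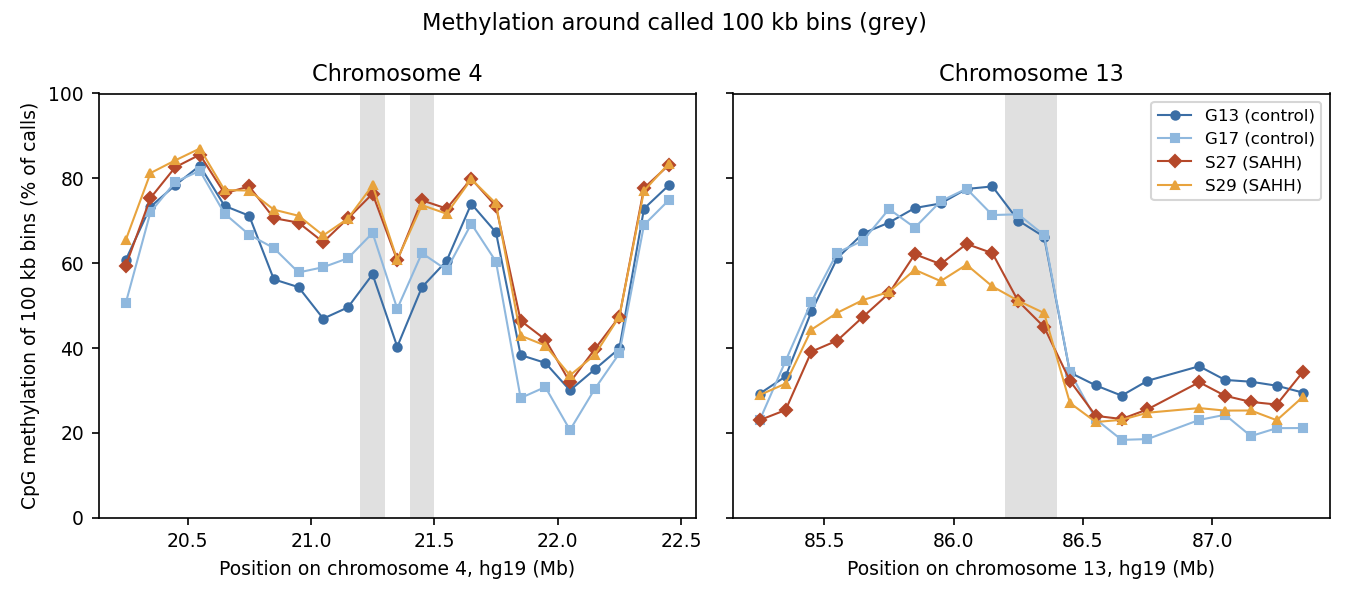
CpG methylation of 100 kb bins (percent of calls, y axis) along parts of chromosomes 4 and 13 (hg19 position in Mb, x axis), 1 line per clone, with the bins called at an adjusted p under 0.05 in grey. In the called chromosome 13 bins SAHH clones S27 and S29 lie at 45.0% to 51.2% and control clones G13 and G17 at 66.2% to 71.5%, and in the called chromosome 4 bins the SAHH clones lie at 73.7% to 78.4% and the controls at 54.4% to 67.1%.

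By Pearson's r the SAHH clones were the most alike pair and the control clones the least alike, while the root mean square difference was largest between G17 and S27 (13.7 points, against 13.4 between G13 and G17). Across 1098075 tiles, which are not independent replicates, Pearson's r was 0.939 between S27 and S29 and 0.884 between G13 and G17. Between groups it was 0.936 for G13 with S27, 0.919 for G13 with S29, 0.897 for G17 with S27 and 0.901 for G17 with S29. Each pair with G17, the shallowest clone, had a lower r than each pair without it. Over the 157581 tiles with at least 50 calls in each clone, r was 0.963 between S27 and S29 and 0.932 between G13 and G17. The low r of the control pair can therefore not be told apart from the depth of G17. Tile levels of S27 and S29 averaged 2.49 and 1.60 points above G13, and 6.64 and 5.75 points above G17, while G17 averaged 4.15 points below G13.

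In the authors' deposited table of expression, 25 genes were higher and 75 lower in SAHH clones among 100 genes with an adjusted p under 0.1. At an adjusted p under 0.05 the authors' deposited table held 14 higher and 46 lower genes. AHCY, the gene of the overexpressed enzyme, had a log2 fold change of 1.76 with a standard error of 0.21 (3.39-fold, DESeq2 adjusted p 1.066e-13) in the authors' deposited table. The table has 1 value for AHCY and does not divide it between the construct and the chromosomal gene.

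The gene with the highest value in the authors' deposited table was CTLA4, an inhibitory receptor best known from T cells, with a log2 fold change of 1.77. It was followed by AHCY, CPS1 at 1.52 (the mitochondrial enzyme of the first step of the urea cycle), PYHIN1 at 1.48 (an interferon-inducible protein), DOCK10 at 1.47 and AJAP1 at 1.13 (a protein of adherens junctions) in the authors' deposited table. The other higher genes past an adjusted p of 0.05 in the authors' deposited table had log2 fold changes from 1.01 down to 0.87. They were SCIN (an actin-severing protein), KCNN3 (a calcium-activated potassium channel), C4orf19, IMPG2, COL12A1 (a collagen chain), TLR3 (a receptor for double-stranded RNA), RFX6 (a transcription factor) and IGFN1. That makes 14 genes, so the rule's 15 was not reached.

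The lowest value in the authors' deposited table was that of SOX3, a transcription factor of the SOX family, with a log2 fold change of -2.26 and a standard error of 0.19 (DESeq2 adjusted p 2.206e-27). It was the one gene with an absolute log2 fold change of at least 2. KIAA2022 (now NEXMIF) followed at -1.42 and COL2A1, the type II collagen of cartilage, at -1.26 in the authors' deposited table. HS3ST5 (a heparan sulfate sulfotransferase) at -1.21, SOX21 (another SOX factor) at -1.19, DSCR6 (now RIPPLY3) at -1.18, KCNQ1 at -1.17, PCDH20 (a protocadherin) at -1.14, SCUBE2 at -1.11 and EPHA3 (an ephrin receptor) at -1.09 came next in the authors' deposited table. PTP4A3 at -1.09, SFRP2 at -1.08, MAGEE1 at -1.08, MDK (midkine, a heparin-binding growth factor) at -1.07 and RHOD at -1.06 completed the 15 lowest in the authors' deposited table.

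**Figure D4:**
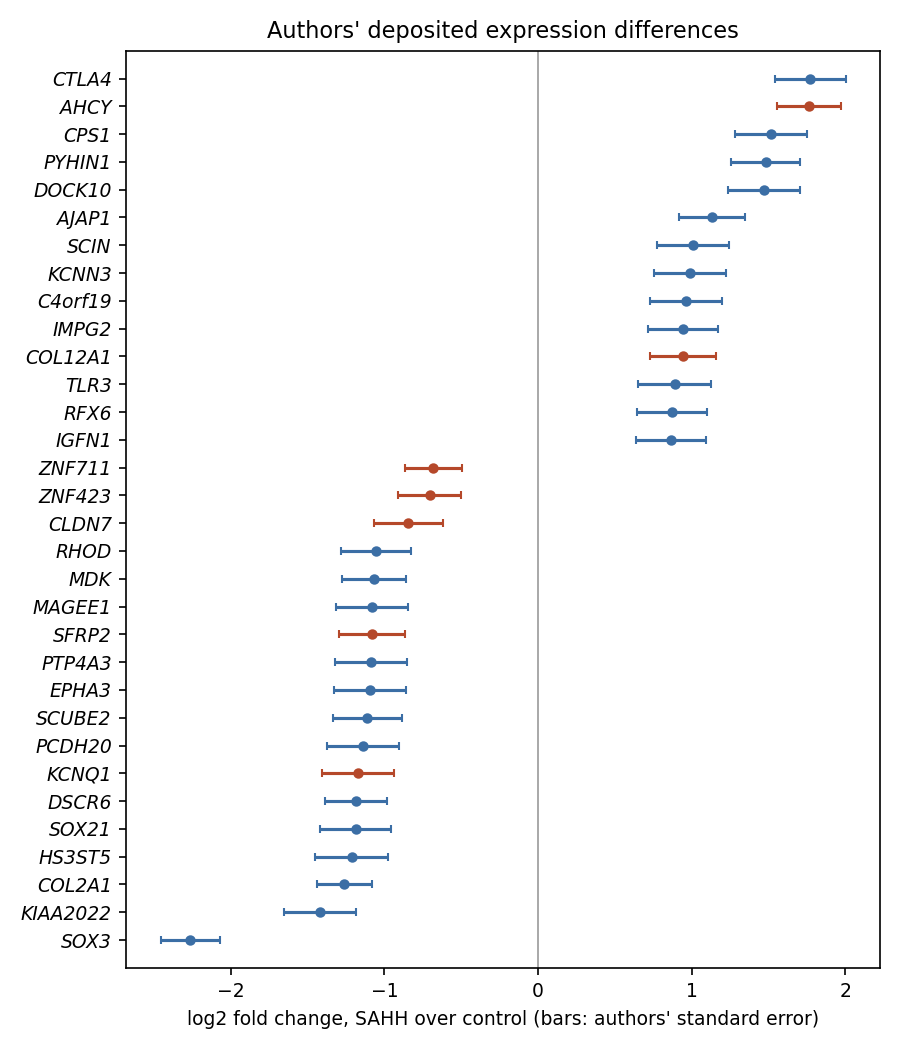
log2 fold changes of SAHH over control clones (x axis) with the authors' standard errors (bars) for the 32 genes named by size or by a fixed list, from the authors' deposited table. Genes of the fixed lists are in red and the others in blue, and values run from -2.26 for SOX3 to 1.77 for CTLA4.

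Of the 17 gene lists fixed beforehand, 6 had a member in the authors' deposited table. The methionine and S-adenosylmethionine cycle had 1 of 25 genes, AHCY. Of 38 imprinted genes 1 was in the authors' deposited table, KCNQ1, a potassium channel gene, which was lower. Zinc finger genes had ZNF423 at -0.71 and ZNF711 at -0.68, with DESeq2 adjusted p-values of 0.079 and 0.0576 in the authors' deposited table. Cell cycle and tumour suppressor genes had 1 of 35, SFRP2, a secreted WNT antagonist, which was lower. Kidney and epithelial genes had 1 of 27, CLDN7, a claudin of tight junctions, at -0.84 in the authors' deposited table. Extracellular matrix genes had COL12A1 at 0.95, taken in by a prefix meant for type I collagen. None of the 21 genes of DNA methylation and demethylation, such as the DNMT and TET enzymes, was among the 100 genes of the authors' deposited table, and neither were any of the 25 histone methyltransferases and demethylases, the 44 germline and cancer-testis genes, the 31 interferon-stimulated genes or the 23 genes of the integrated stress response. The lists of HOX genes, clustered protocadherins and WNT, TGF-beta and FGF genes also had 0 members there. So did those of 38 neuronal genes, 24 markers of other cell types and 15 pluripotency genes. Lists of chosen genes do not hold every gene of a kind, so others of that kind can be among the 100. PYHIN1, the interferon-inducible one named above, is such a case. A gene outside the authors' deposited table has no value here, and whether it was measured is not known from it.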

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

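All tests of explanations in this part were chosen after the results they bear on had been seen. Signals outside chromosomes 1 to 22 and X were compared in the same way, and 2 lay higher in both SAHH clones than in both controls. Calls on the mitochondrial genome, which serve as an upper limit of bisulfite non-conversion, were 4.04% ± 0.48 methylated in SAHH clones and 3.22% ± 0.17 in controls (SD, n = 2 each), a difference of 0.82 points. Calls on unplaced and alternate contigs were 48.8% ± 0.22 methylated in SAHH clones and 44.1% ± 3.64 in controls, a difference of 4.72 points. Much of that came from G17, at 41.5%, while G13 was at 46.6%.

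The higher CpG methylation of both SAHH clones could come from incomplete bisulfite conversion, from unequal coverage or from the depth and quality of the files. It could also come from differences between single clones or from SAHH. Taking the mitochondrial level out of each clone left a difference of 4.52 of the 4.66 points, so non-conversion of that size does not account for it. With each of the 1098075 tested 1 kb tiles counted once, the difference was 4.12 points, so unequal coverage among those tiles does not account for it either. The other tiles of the 2785273 with a listed site were too thin to enter, and for them this stays open. Depth and file quality also followed the groups. Kept calls rose in the same order as total methylation, from G17 (58906455) and G13 (130868902) to S29 (168682065) and S27 (187933244). Rows estimated as misplaced were 11.9% in G13, 7.16% in G17 and 3.18% in S27, with S29 as the reference. With the files as deposited the difference was 4.54 points. Total levels were not compared at equal depth, so this explanation stays open. The 2 control clones lay 3.17 points apart, and 2 clones against 2 give no p under 0.333. Depth or file quality, clonal differences and an effect of SAHH thus cannot be told apart. An effect of SAHH stays an untested hypothesis in this design.

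Most of the 100 kb bins called higher, and 7 of the 9 tiles with an adjusted p under 0.05, lay in very deep sequence, the 7 tiles all between 46300001 and 46500000 of chromosome 16. A candidate explanation is that the test gives all depths 1 prior spread, which is too small where very many calls make clone differences exceed counting noise. With the dispersion moderated along depth, 0 of those 7 tiles stayed past the threshold, and their smallest adjusted p was 0.71 in the limma-moderated test. The level itself was higher in both SAHH clones than in both controls in 73 of the 100 tested tiles of that stretch.

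Tile calls set the clones apart along another line than the groups. The real split called 3 tiles, and with 3 possible splits a share under 0.05 cannot be had. As many tiles as that or more were called by 2 of the 3 splits. The highest other count was 567, for G13 and S27 (numbered replicate 1 of each group, in accession order only) against G17 and S29 (replicate 2). The splits were run with 1 prior spread for all depths alone, so whether the 567 calls stay with moderation along depth is not known. At an unadjusted p under 0.05 the order was the other way, with 74338 tiles for the real split, 62344 for that one and 28068 for the third. Unequal depth does not account for all of the 567 calls, since after thinning to the shallowest clone the split of G13 and S27 called 31 tiles and the real one 4. Whether copy number differences account for these calls cannot be decided here. Of the 567 tiles, 16.6% lay in 1 Mb bins with an absolute log2 depth ratio over 0.25 between the pairs, against 16.2% of all tested tiles. That ratio compares the means of the pairs, so a change in 1 clone can stay under 0.25. The median ratio for the 567 tiles was 0.133, against 0.101 over all tested tiles. It lay at the upper end of the range of 0.070 to 0.133 in 1000 random draws of bins. Copy number thus stays open, as does a part from depth. No biological explanation was tested.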

How the results depend on the processing

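The total, CpG density and level class differences kept their direction in the settings run for each and with any clone left out. Density classes had 2 other settings and level classes 1. The total difference ranged from 4.12 to 6.97 points over 8 settings and from 3.08 to 6.24 points with a clone left out. The 6.97 points came from the 28323 sites with at least 10 calls in every clone, of 45749911. Controls averaged 37.4% and SAHH clones 44.3% there, below the level of all sites, so that value does not describe the whole genome. No permutation test of 2 clones against 2 can pass a threshold, so this speaks of direction alone. Both SAHH clones were above both controls on 22 or 23 chromosomes. The median difference of bins was 4.01 to 4.51 points, and 2.39 to 6.58 points with a clone left out.

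Tile calls were not stable, and the cause was not tested. Against 3 gained and 0 lost, none were called with at least 10 or at least 50 calls per clone, with 5 kb tiles, with each tile's own dispersion, with edgeR, or, chosen after seeing the data, with the dispersion moderated along depth (0 in each). No minimum difference gave 9 gained. A minimum of 25 points gave 2, differences relative to the median tile 2, thinning to the shallowest clone 4 and sites covered in all 4 clones 3, with 0 lost in each. The pooled Fisher's exact test, which ignores the spread between clones, gave 43537 gained and 4749 lost. The files as deposited, also added after seeing the data, gave 77 and 6. With a clone left out there were 0 to 51 gained and 0 to 9 lost, where the lone clone of a group is assumed to vary like the other group. Of the 3 tiles, none was past the threshold in each setting.

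Bins called higher were 13, with 4 in 1 Mb bins and 0 to 24 with a clone left out. Bins called lower were 2, with 8 along depth, 0 with at least 5000 calls, 0 in 1 Mb bins and 0 to 34 with a clone left out. In the authors' table, an absolute log2 fold change of at least 2 left 0 of 25 higher and 1 of 75 lower genes, and an adjusted p under 0.05, added after seeing the data, left 14 and 46. Promoter windows were not run for want of an hg19 annotation. No paired analysis was possible because the labels give the clones no shared replicate number, and the numbers used here follow accession order. At 1.29 calls per cytosine in G17, single cytosines were not tested.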

Other observations

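The comparisons and settings of this part were chosen after the data were seen. Regions of lower methylation in SAHH clones were rare and clustered. Of 28098 bins of 100 kb with at least 500 calls in each clone, 246 (0.88%) had both SAHH clones below both controls, and these included 41 stretches of 2 or more neighbouring bins. The 3 longest stretches were on chromosome 13. From 62500001 to 64700000, 22 neighbouring bins averaged 32.6% ± 2.58 in SAHH clones and 51.6% ± 14.6 in controls (SD, n = 2 each), with G13 at 41.3% and G17 at 62.0%. From 85300001 to 86500000, 12 bins averaged 48.7% in S27 and in S29 and 62.8% in G13 and 62.7% in G17, a stretch that holds the 2 bins called lower. From 92300001 to 93500000, 12 bins averaged 45.8% ± 1.75 in SAHH clones and 56.7% ± 3.49 in controls. The longest on another chromosome had 9 bins, on chromosome 21 from 17700001 to 18600000, with S29 at 37.4%, S27 at 54.0%, G17 at 56.4% and G13 at 60.3%. No test beyond that of single bins was run on these stretches.

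The 2 control clones differed from each other along the same levels as the groups did. In tiles of 60 to 70% mean level G13 was at 65.8% and G17 at 58.9%, and in tiles of 90 to 100% they were at 91.6% and 91.3%. On the log2 odds scale the SAHH-minus-control difference was 0.57 in tiles of 0 to 10%, 0.31 in tiles of 40 to 50%, 0.44 in tiles of 80 to 90% and 0.22 in tiles of 90 to 100%. The clones averaged 3.85% to 6.70% in tiles of 0 to 10%, near their mitochondrial levels of 3.10% to 4.38%. Levels by class were not corrected for non-conversion, so its part in the 0.57, or in the 2.02 points there, is not known.

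Relative depth, the median calls of the 1 Mb bins of a chromosome over the median of all 1 Mb bins, set single clones apart on some chromosomes. Chromosome 8 was at 0.94 in G13 and 0.68 to 0.70 in the other clones. Chromosome 2 was at 0.76 in G17 and 0.98 to 1.03 in the others, and chromosome 11 at 0.91 in G17 and 0.63 to 0.67 in the others. Chromosome 3 was at 0.83 in S27 and 0.63 to 0.65 in the others, and chromosome 4 at 0.88 in S29 and 0.62 to 0.65 in the others. G17 and S29 were above G13 and S27 on chromosome 19 (2.03 and 1.97 against 1.49 and 1.65), on chromosome 16 (1.31 and 1.19 against 0.92 and 0.99) and on chromosome 6 (1.60 and 1.62 against 1.42 and 1.34), among others.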
